A study of Mus musculus with 20 samples.

How the data were processed

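Total RNA from kidney and liver of male C57BL/6 mice, 5 labelled Lxrα-/- and 5 labelled wild type, was extracted with Trizol, and libraries were made from 3 ug of total RNA with the NEBNext Ultra RNA kit, per the labels. Sequencing was on an Illumina HiSeq instrument. The processing notes name HISAT2 2.0.5, StringTie and DESeq2 1.16.1 with genome build mm10, but give no role or order for them, and neither the counting tool nor the use of strand is given in the sources used here. Ages, diet and littermate status are not in the labels either.

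The deposited count table holds raw counts per gene, in whole numbers, for 54532 genes and 20 libraries, of which 20087 genes have no count in any library. A second deposited table holds log2 FPKM values of 15454 genes, which are the genes with a count in every library. Its values equal log2 of FPKM computed from the counts plus an offset of each library between -0.727 and 0.358, with a largest deviation of 0.0051 for genes over 50 counts. All results rest on the counts, and the log2 FPKM values served in an alternative. Total counts ran from 26590469 to 32033103 in labelled knockout kidney, 23421561 to 32221055 in wild-type kidney, 23863994 to 35376342 in labelled knockout liver and 25502268 to 31790913 in wild-type liver. Intervals and floors cover counting error only.

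Libraries were grouped by genotype and tissue as labelled. For kidney and for liver, the 10 libraries were fitted alone with edgeR 4.0.16 in R 4.3.3, with filterByExpr (minimum count 10), TMM scaling, the quasi-likelihood F test (QL) and the adjustment of Benjamini and Hochberg (BH), and a gene was called at an adjusted p under 0.05. Calls with an absolute log2 fold change of at least 1 were counted as well. The difference between tissues was the genotype effect in kidney minus that in liver, from a fit of all 20 libraries with a mean per group. Standard errors were computed from the log2 fold change and its QL statistic. CPM values in the text are counts scaled by library size and TMM factor. Exceptions are the tissue marker means, Xist and Ddx3y, and the lower bound for Moxd1, which were scaled by library size alone. Gene positions, strands and biotypes are those in the count table. With 5 against 5 libraries, chance makes the groups not overlap for 0.794% of genes.

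Tests, alternatives, gene lists and the rule for named genes were fixed before the data were examined, except where the text says otherwise. In all, 34 lists with 483 distinct symbols were written, of which 482 are in the count table. Some lists share members, so they are not independent. Scd1 and Srebf1 are in the LXR target and fatty acid synthesis lists, and Cd5l is in the LXR target and Kupffer cell lists. C6 is in the male-biased and Kupffer cell lists. Slco1a1 is in the male-biased, bile acid and transporter lists, and Slc22a6 in the proximal tubule and transporter lists. A list was tested where at least 5 members passed the filter, with camera of limma 3.58.1 at a preset correlation of 0.01, and the p values were adjusted by BH over the lists of a comparison. Camera with an estimated correlation and fry were the alternatives. Named genes were Nr1h3 and Nr1h2, per tissue the 10 highest and 10 lowest protein-coding genes by log2 fold change among those called, with a mean of at least 1 CPM and no overlap between genotypes, up to 4 members with the smallest p of each list described, 5 genes at each end of the difference between tissues, and the 10 genes with the smallest product of p among those called in both tissues. Madd, Lpl, Srebf1, Abca1, Abcg5, Abcg8, Cyp7a1, Clec4f and Vsig4, the liver value of Cd4, and the genes named only in the closing section were chosen after their values were seen. Some genes that the rule names are not reported here. Shares have 95% Wilson intervals. Genes within 10 Mb of Nr1h3 were compared with the rest by Fisher's exact test, with windows of 5 and 20 Mb as alternatives.

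The alternatives were the DESeq2 1.42.0 Wald test, DESeq2 size factors in edgeR, no TMM scaling, no filter beyond 1 count, a filter at a mean of 1 CPM, limma voom with quality weights, protein-coding genes alone, all 20 libraries in 1 fit, limma-trend on the log2 FPKM table, the title number as a replicate block, leaving out genes near Nr1h3, and leaving out each replicate in turn. Titles number the wild-type mice 1, 3, 4, 5 and 6 and the labelled knockout mice 1 to 5. The labels do not say that equal numbers of different genotype share anything, so the block by number served as an alternative alone. Kidney and liver of equal genotype and number were taken as 1 mouse for the block by mouse, which the labels do not spell out. Fits without wild-type kidneys 1 and 3, without labelled knockout livers 4 and 5, and without mitochondrially encoded genes, and camera on the difference between tissues, were chosen after seeing the data.

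The pipeline was tested on simulated data with 200 genes changed among those tested. In kidney it called 44 of 100 genes changed 2-fold and 96 of 100 changed 4-fold, with 9 false calls among 149. In liver it called 75 and 97 of 100, with 5 false among 177, and for the difference between tissues 30 and 92 of 100, with 3 false among 125. In each tissue camera gave a p under 0.05 for 3 of 99 lists without change. These were random lists of genes simulated independently of each other. They do not show how camera behaves where the members of a list vary together. As a check of tissue, hepatocyte markers averaged 8102 to 12285 CPM in the livers and 8.09 to 57.4 CPM in the kidneys, and proximal tubule markers 1575.5 to 4206 CPM in the kidneys and 6.91 to 9.72 CPM in the livers. No library was a copy of another. No library was left out of the results reported.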

Results

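RNA was sequenced from the kidney and the liver of male C57BL/6 mice, which gave 20 libraries in 4 groups of 5. Libraries of equal genotype and title number were taken as 1 mouse. This makes 10 mice, 5 labelled as lacking Lxrα and 5 labelled as wild type. Lxrα, encoded by Nr1h3, is a nuclear receptor that is activated by oxysterols and drives genes of sterol efflux and fatty acid synthesis. The labelled knockout mice are numbered 1 to 5 and the wild-type mice 1, 3, 4, 5 and 6. Total counts per library ran from 23421561 to 35376342. Group values are mean CPM (counts scaled to a common library size) ± SD with n = 5, and fold changes are log2 of labelled knockout over wild type with the standard error (SE). Adjusted p values for genes are from edgeR's quasi-likelihood test and those for gene lists from camera, both after Benjamini and Hochberg. The design implies 3 questions: what differs by genotype in kidney, what differs in liver, and where the difference depends on the tissue.

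The targeted gene was examined first. Nr1h3 (ENSMUSG00000002108, mm10 chromosome 2, positions 91184061 to 91202834) had more counts in the labelled knockout libraries, in both tissues. In kidney it stood at 126 ± 21.7 CPM against 52.1 ± 2.27 in wild type (log2 fold change 1.27, SE 0.16, edgeR adjusted p = 0.00209). In liver it stood at 167 ± 18.0 CPM against 98.2 ± 13.6 (0.76, SE 0.12, edgeR adjusted p = 0.00277). All 5 labelled knockout libraries lay above all 5 wild-type libraries in each tissue. Counts per gene do not show which exons were read, and the deleted part of the gene is not given in the labels, so this measurement alone neither identifies the allele nor checks the labels. Of the targets of the receptor, 6 of 20 were lower in labelled knockout liver and none was higher, with Scd1 at -4.79, Pltp at -3.43 and Cd5l at -8.45. The other 14 were not called, among them Abca1 (0.09), Abcg5 (-0.24) and Abcg8 (0.14). In kidney 1 of 15 was lower, with a median of 0.03 (camera adjusted p = 0.645). Only a part of the targets thus bears on the labels in liver, and the list does not in kidney. Every direction below is given by the genotype as labelled. Nr1h2, which encodes the related receptor Lxrβ, differed by 0.05 (SE 0.19, edgeR adjusted p = 0.884) in kidney and by -0.08 (SE 0.12, 0.763) in liver. Nr1h2 in kidney turned to -0.03 without wild-type library 6 and to -0.0046 without labelled knockout library 3, and Nr1h2 in liver turned to 0.0065 without wild-type library 1.

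The neighbours of Nr1h3 on one side were higher too. Acp2, which encodes a lysosomal acid phosphatase and starts at position 91202885, was higher by 1.33 (SE 0.13, edgeR adjusted p = 0.000856) in kidney and by 1.23 (SE 0.10, 2.74e-05) in liver. Ddb2, a DNA damage recognition gene at positions 91211572 to 91236982, was higher by 0.96 (SE 0.21, 0.0362) in kidney and by 2.15 (SE 0.16, 7.72e-06) in liver. The annotated spans of Acp2 and Ddb2 overlap on opposite strands, and the sources used here do not say whether counting used strand, so reads in the overlap cannot be assigned with certainty. Madd, on the other side of Nr1h3, differed by 0.00 in kidney and -0.07 in liver and was not called in either tissue (edgeR adjusted p = 0.997 and 0.852). Within 10 Mb of Nr1h3 and apart from it, 4 of 88 tested genes were called in kidney (odds ratio 2.08, 95% interval 0.550 to 5.56, two-sided Fisher's exact p = 0.137) and 3 of 82 in liver (0.592, 0.119 to 1.80, p = 0.488). Acp2 and Ddb2 are counted among the called genes of each tissue. They are the only ones within 5 Mb, where 2 of 64 were called in kidney and 2 of 56 in liver. The kidney call of Ddb2 was lost without wild-type library 4 or 5 or labelled knockout library 1, 2, 3, 4 or 5, with edgeR adjusted p up to 0.104.

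**Figure D1:**
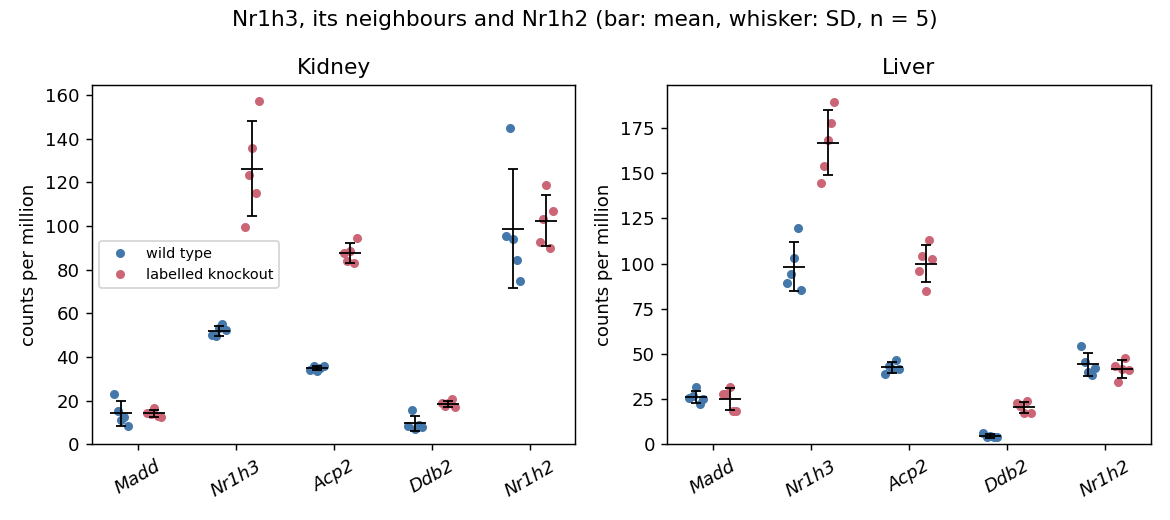
CPM of Nr1h3, its neighbours Madd, Acp2 and Ddb2, and Nr1h2 in kidney (left) and liver (right), with 1 point per library, bars for the mean and whiskers for the SD (n = 5). Nr1h3 and Acp2 are higher in the 5 labelled knockout libraries than in the 5 wild-type libraries of each tissue, and Madd is not called.

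In kidney, 14 of 20 interferon-stimulated, 9 of 16 matrix and 8 of 12 proliferation genes were lower in the labelled knockout libraries, and 3 of 7 male-biased genes were higher. Camera called these lists, but none of them with an estimated correlation (adjusted p from 0.0699 to 0.120). The antiviral regulator Irf7 stood at 8.01 ± 1.66 CPM against 29.0 ± 6.90 in wild type (-1.85, SE 0.20, edgeR adjusted p = 0.00146). Col1a1, which encodes a chain of type I collagen, stood at 6.18 ± 0.984 against 46.5 ± 22.1 CPM (-2.91, SE 0.36, 0.00209). Cyp4a12a, a male-specific fatty acid hydroxylase, stood at 205 ± 79.7 against 13.1 ± 5.63 CPM (3.97, SE 0.40, 0.00100). In all, 373 of 16500 tested genes were called, 65 higher and 308 lower, of which 49 and 274 differed by at least 1 on the log2 scale. The split was 38 higher and 358 lower without TMM scaling, 306 and 845 by DESeq2, and 801 and 1350 by voom. The 5 libraries of each genotype did not overlap for 1141 genes (6.92%, where chance gives 0.794%).

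Of 20 interferon-stimulated genes, 14 were lower in labelled knockout kidney and none was higher (19 lower when adjusted over the list alone), with a median log2 fold change of -1.26. Besides Irf7 these included Rtp4 (-1.75, edgeR adjusted p = 0.00336), Ifit1 (-1.80, 0.00374) and Oas1a (-1.69, 0.00668). The list was called by camera (adjusted p = 2.19e-29) but not with an estimated correlation (adjusted p = 0.0699). Of 16 extracellular matrix and fibroblast genes, 9 were lower and none higher (14 lower when adjusted over the list alone), among them Col3a1 (-2.57, edgeR adjusted p = 0.00208), Col1a2 (-2.30, 0.00209) and Col5a1 (-2.03, 0.0105). Camera gave an adjusted p of 2.40e-19, and 0.0699 with an estimated correlation. Of 12 proliferation genes, 8 were lower (10 when adjusted over the list alone), led by Mki67 (-2.10, edgeR adjusted p = 0.0108), Rrm2 (-1.40, 0.0117) and Mcm5 (-1.17, 0.0127). The camera adjusted p was 4.01e-12, and 0.120 with an estimated correlation. Of 13 lymphocyte and neutrophil markers, 4 were lower (8 when adjusted over the list alone), namely Cd4, Cd3g, Gzma and Nkg7, with log2 fold changes from -2.42 to -1.43 (camera adjusted p = 6.29e-06, and 0.0776 with an estimated correlation). Without libraries 4 or 5 of the labelled knockout, the Cd4 call was lost, and the calls of Cd3g, Gzma and Nkg7 were lost in 7 of the 10 fits that left out 1 library, the exceptions being wild-type 3 and 6 with labelled knockout 2 for Gzma and Nkg7 and wild-type 1, 3 and 6 for Cd3g (highest edgeR adjusted p between 0.0688 and 0.127).

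Few markers of the cell types of the kidney were called, and none of their lists with an estimated correlation. Of 15 proximal tubule markers, 14 had positive fold changes, with a median of 0.45, and 1 was called, the organic anion transporter Slc22a6 (1.11, SE 0.24, edgeR adjusted p = 0.0332, 2 called when adjusted over the list alone). These markers were averaged after scaling by library size alone. Their mean lay between 1575.5 and 3122 CPM in the wild-type kidneys and between 3527 and 4206 CPM in the labelled knockout kidneys. This tissue measure thus moved with genotype beside every group named here. TMM factors of the wild-type kidneys ran from 0.795 to 1.30, and how much of the gap comes from scaling was not tested. Camera called the list (adjusted p = 1.45e-05, and 0.175 with an estimated correlation). Endothelial markers had a median of -0.79 with 1 of 10 called, Cdh5 (-1.08, edgeR adjusted p = 0.0402, 8 lower when adjusted over the list alone), and glomerular markers a median of -0.80 with 0 of 9 called by edgeR (6 lower when adjusted over the list alone). Their camera adjusted p values were 1.46e-06 and 9.99e-05, and both were 0.215 with an estimated correlation. General macrophage markers had a median of -0.58 with 0 of 14 called (0 when adjusted over the list alone), with a camera adjusted p of 0.00117, and 0.312 with an estimated correlation. Slc22a6 and Cdh5 each kept the call in 3 of the 10 fits without 1 library, those without wild-type 3, wild-type 6 or labelled knockout 2 (edgeR adjusted p up to 0.101 and 0.124 in the others).

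Male-biased genes, a list taken from liver, were higher for 3 of 7 tested in kidney (5 when adjusted over the list alone), namely Cyp4a12a, Cyp4a12b (1.87, edgeR adjusted p = 0.0228) and the organic anion transporter Slco1a1 (2.25, 0.0261). Camera gave an adjusted p of 9.60e-10, and 0.0699 with an estimated correlation. Of 5 female-biased genes tested in kidney, none was lower and 1 was higher, Cyp2a4 (2.39, edgeR adjusted p = 0.00337). When adjusted over the list alone, 1 was higher and 1 lower. The median of these genes was 0.16, and camera did not call the list (adjusted p = 0.124). Of 15 organic anion and cation transporters, Slco1a1 and Slc22a6 were higher (4 when adjusted over the list alone, camera adjusted p = 0.00117, and 0.215 with an estimated correlation). Both are already counted above, Slco1a1 in the male-biased list and Slc22a6 in the proximal tubule list. Among 15 LXR target genes, 1 was called lower in kidney by edgeR and none higher (1 higher and 2 lower when adjusted over the list alone). The median of this list was 0.03 and its mean -0.24, and camera pointed towards lower without calling it (adjusted p = 0.645). Of 24 genes of fatty acid and triglyceride synthesis none was called in kidney (1 higher when adjusted over the list alone), and their median was 0.13. Camera called 17 of 29 tested lists in kidney, 9 towards higher and 8 towards lower, and none with an estimated correlation. The other lists called towards higher, with their adjusted p under an estimated correlation, were fatty acid synthesis (0.466), cholesterol synthesis (0.373), bile acid genes (0.145), fatty acid oxidation (0.603), drug metabolism (0.376) and endoplasmic reticulum stress (0.284), and immediate early genes were called towards lower (0.594). Among these, the camera call was lost for immediate early genes without wild-type 3 (adjusted p = 0.144), for fatty acid synthesis without wild-type 3 (0.0935), wild-type 6 (0.0638) or labelled knockout 3 (0.0818), for fatty acid oxidation without wild-type 3 (0.0874) and for endoplasmic reticulum stress without wild-type 1 (0.0897), wild-type 3 (0.0686) or labelled knockout 5 (0.0586). The endoplasmic reticulum stress call was also lost with the title number as a replicate block (camera adjusted p = 0.0609).

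The strongest kidney genes outside these lists included Azgp1, a secreted zinc-binding glycoprotein (3.17, SE 0.31, edgeR adjusted p = 0.000856), Cntnap5a (4.41, SE 0.53, 0.00208), Ctxn3 (3.37, SE 0.44, 0.00278), Apoh, a plasma glycoprotein (2.80, SE 0.33, 0.00208), Col19a1 (2.98), Cpe (2.34) and Chrdl1 (2.34). Those lowest in the labelled knockout included the prolactin receptor Prlr (-2.82, SE 0.62, 0.0338), Neil3 (-2.72), Oas2 (-2.71), Pimreg (-2.61), Ifi208 (-2.61), Ms4a4b (-2.49), Dtl (-2.47) and Col6a2 (-2.46). Ifi208 and Cyp2a4 belong to families of similar genes, whose reads cannot be assigned with certainty. The calls of Prlr, Neil3, Oas2, Pimreg, Ifi208, Col19a1, Slco1a1 and Cyp4a12b were lost in at least 1 fit without 1 library. The libraries concerned were labelled knockout 4 for Neil3 and Col19a1, labelled knockout 1, 4 or 5 for Oas2, labelled knockout 1, 3, 4 or 5 for Pimreg, Slco1a1 and Prlr, with wild-type 5 for Prlr, wild-type 4 or 5 or labelled knockout 5 for Cyp4a12b, and all but wild-type 6 and labelled knockout 2 for Ifi208 (highest edgeR adjusted p between 0.0503 and 0.129).

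The number of kidney calls depended on single libraries. It was 175 without wild-type library 4, 157 without wild-type 5, 921 without wild-type 6, and 129, 150, 99 and 104 without labelled knockout 1, 3, 4 and 5. Wild-type kidney 3 had 50.8% mitochondrial counts (95% Wilson interval 50.7% to 50.8%) and wild-type kidney 1 had 7.21% (7.21% to 7.22%), against 12.6% to 21.1% in the other 8 kidneys. Without both, 590 genes were called, 177 higher and 413 lower, of which 318 were among the 373, and interferon-stimulated genes were lower for 14 of 20, matrix genes for 9 of 16 and proliferation genes for 9 of 12. In that fit 5 lists lost the camera call, namely bile acid genes (adjusted p = 0.0961), fatty acid oxidation (0.228), drug metabolism (0.148), immediate early genes (0.359) and endoplasmic reticulum stress (0.291).

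In liver, 15 of 24 genes of fatty acid synthesis, 6 of 20 LXR targets, 17 of 20 interferon-stimulated genes and 4 of 6 female-biased genes were lower in the labelled knockout libraries. In turn, 10 of 25 genes of cholesterol synthesis and 5 of 12 male-biased genes were higher, though camera did not call the cholesterol list with an estimated correlation (adjusted p = 0.258). Scd1, the stearoyl-CoA desaturase, stood at 193 ± 91.9 CPM against 5345 ± 1767 in wild type (-4.79, SE 0.38, edgeR adjusted p = 1.92e-05). Cd5l, a macrophage glycoprotein and LXR target, stood at 0.240 ± 0.174 against 90.7 ± 28.2 CPM (-8.45, SE 0.37, 1.22e-07). Cyp7b1, an oxysterol hydroxylase with male-biased expression, stood at 783 ± 115 against 47.4 ± 22.1 CPM (4.05, SE 0.28, 5.01e-06). In all, 893 of 14822 tested genes were called, 288 higher and 605 lower, of which 172 and 367 differed by at least 1 on the log2 scale. Without TMM scaling the split was 216 higher and 766 lower. It was 538 and 870 by DESeq2, and 107 and 200 with the title number as a replicate block. The libraries of the genotypes did not overlap for 1030 genes (6.95%, where chance gives 0.794%).

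Of 24 genes of fatty acid and triglyceride synthesis, 15 were lower and none was higher (19 lower and 1 higher when adjusted over the list alone), with a median of -1.21. They included the elongase Elovl5 (-2.18, SE 0.23, edgeR adjusted p = 0.000148), the acetyl-CoA carboxylase Acaca (-1.39, SE 0.15, 0.000170) and the malic enzyme Me1 (-1.94, SE 0.21, 0.000216). The list was called by camera (adjusted p = 1.33e-23) and with an estimated correlation (0.0148). Of 20 LXR target genes, 6 were lower and none was higher (9 lower when adjusted over the list alone). They were Cd5l, Scd1, the phospholipid transfer protein gene Pltp (-3.43, SE 0.28, edgeR adjusted p = 2.57e-05), the ubiquitin ligase gene Rnf145 (-1.38, SE 0.19, 0.00104), the lipoprotein lipase gene Lpl (-2.46, 0.00104) and Srebf1 (-1.17, 0.0162), which encodes a master regulator of lipid synthesis. The call of Srebf1 in liver was lost without labelled knockout livers 4 and 5 (edgeR adjusted p = 0.0728). Abca1, the cholesterol exporter of cells (0.09, SE 0.14, edgeR adjusted p = 0.760), and Cyp7a1, the rate-limiting enzyme of bile acid synthesis (0.10, SE 0.38, 0.916), were not called, and Cyp7a1 in liver turned to -0.09 without wild-type library 1 and to -0.38 without labelled knockout library 2. The camera adjusted p of the list was 3.18e-14, and 0.0148 with an estimated correlation. Of 28 genes of fatty acid oxidation and PPARα targets, 7 were lower (10 when adjusted over the list alone), among them the fatty acid transporter Cd36 (-2.48, edgeR adjusted p = 0.000116), Cyp4a14 (-4.26, 0.00237) and Angptl4 (-0.82, 0.00296), whose call was lost with all 20 libraries in 1 fit (0.0847). The camera adjusted p was 2.97e-07, and 0.192 with an estimated correlation.

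Genes of cholesterol synthesis and uptake went the other way. Of 25, 10 were higher and none was lower (17 higher and 1 lower when adjusted over the list alone), with a median of 0.65. They included Msmo1 (1.59, SE 0.21, edgeR adjusted p = 0.000745), Hsd17b7 (1.08, SE 0.16, 0.00191), the squalene epoxidase Sqle (1.36, SE 0.27, 0.00975) and the mevalonate kinase Mvk (1.43, SE 0.29, 0.0106). The call of Sqle in liver was lost without labelled knockout livers 4 and 5 (edgeR adjusted p = 0.0541). Camera gave an adjusted p of 5.67e-10, and 0.258 with an estimated correlation. Of 20 bile acid genes, Cyp7b1 was higher and the uptake carrier Slc10a1 (-1.03, edgeR adjusted p = 0.00638) and the phospholipid transporter Abcb4 (-0.51, 0.0478) were lower (1 higher and 3 lower when adjusted over the list alone). Their median was -0.08 and their mean 0.03, and camera pointed towards lower without calling the list (adjusted p = 0.935). The Abcb4 call held in 2 of the 10 fits without 1 library, those without wild-type 5 or labelled knockout 1, with an edgeR adjusted p of up to 0.138 in the others.

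**Figure D2:**
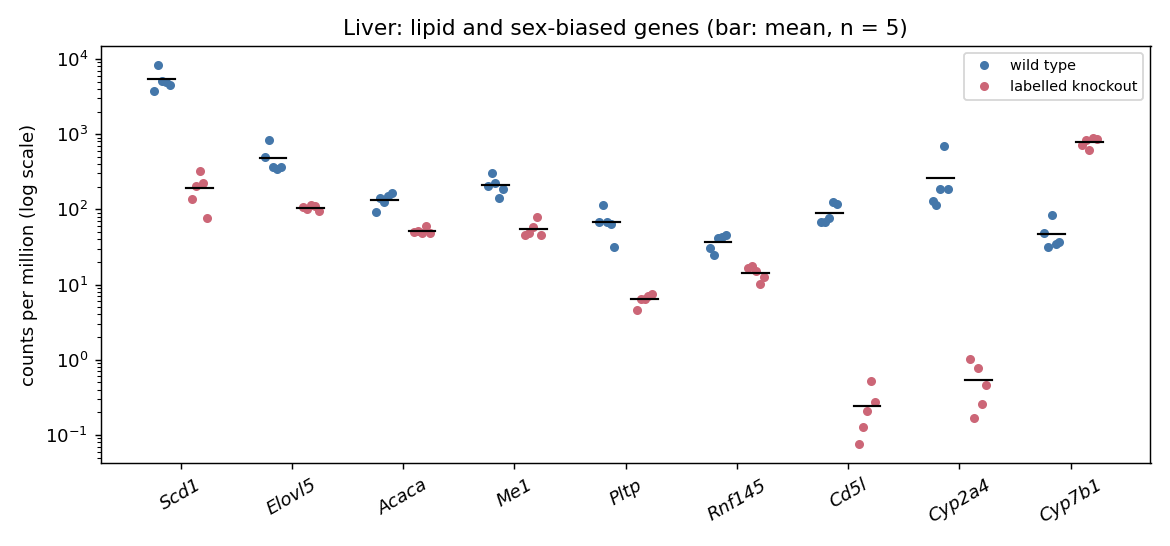
Liver CPM on a log axis for lipid genes (Scd1 to Rnf145), the macrophage gene Cd5l and the sex-biased genes Cyp2a4 and Cyp7b1, with 1 point per library and bars for the mean (n = 5). The 5 labelled knockout libraries lie below the 5 wild-type libraries for every gene drawn except Cyp7b1, where they lie above.

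Some sex-biased genes differed between the genotypes in these male mice. Of 6 tested female-biased liver genes, 4 were lower and none was higher (5 lower when adjusted over the list alone), including the steroid hydroxylase Cyp2a4 (0.537 ± 0.355 against 263 ± 244 CPM, -8.94, SE 0.69, edgeR adjusted p = 1.61e-05), Cyp2b9 (-8.46, SE 0.96, 0.000279) and Hao2 (-8.01, SE 0.99, 0.000551). Hao2 had 6 counts over the 5 labelled knockout libraries, which leaves the size of its fall uncertain. Wild-type liver 5 held the highest value of these 3 genes. Of 12 male-biased genes, 5 were higher and none was lower (8 higher when adjusted over the list alone), including Cyp7b1, the complement gene C6 (2.42, edgeR adjusted p = 0.00145) and the major urinary protein gene Mup7 (11408 ± 3130 against 268 ± 249 CPM, 5.41, SE 0.82, 0.00189). Both lists were called by camera (adjusted p = 9.05e-12 and 3.18e-14) and with an estimated correlation (0.0251 and 0.0478). The genes with the highest fold changes in liver were mostly of the urinary protein family, Mup15 (8.79), Mup8 (7.06), Mup17 (5.97), Mup1 (5.89), Mup12 (5.68) and Mup19 (5.55), whose near-identical copies make the values of single members uncertain. The wild-type mean of Mup17 rested on liver 4, at 258 CPM against 0.487 to 16.1 CPM in the others, and its fold change ran from 5.65 to 10.05 over the alternatives. The call of Mup8 in liver was lost by voom (adjusted p = 0.0672), and that of Mup17 without wild-type 1, wild-type 6 or labelled knockout 4 (edgeR adjusted p up to 0.0765). Moxd1, a monooxygenase-like gene, had 0 counts in the 5 wild-type livers and 87.6 ± 75.3 CPM in the labelled knockout livers, at least 4010.5-fold higher against a floor of 3 counts over the group. The odorant-binding protein gene Obp2a (7.13, SE 0.80) and Cyp21a1 (6.19, SE 0.79) rested on 4 wild-type counts each. The lowest genes further included Slc22a26 (-7.96), Kcna2 (-6.39), Slc22a27 (-5.71), Cyp2a22 (-5.14) and Fam19a2 (-5.06), of which Kcna2 had 6 counts in the labelled knockout livers.

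Camera called 4 lists of immune genes towards lower in labelled knockout liver, of which the interferon and the lymphocyte list held with an estimated correlation. Of 20 interferon-stimulated genes, 17 were lower and none was higher (18 lower when adjusted over the list alone), with a median of -0.98. They included the interferon response regulator Usp18 (-1.83, SE 0.16, edgeR adjusted p = 3.27e-05), Ifi44 (-2.29, SE 0.28, 0.000450) and Ifit3 (-1.54, SE 0.21, 0.000915). The camera adjusted p was 5.72e-25, and 0.0118 with an estimated correlation. Of 13 lymphocyte and neutrophil markers, 7 were lower, led by Gzma (-2.16, edgeR adjusted p = 0.00251) and Cd79a (-1.66, 0.00254), and 1 was higher, Cd4 (1.13, 0.0377), with 10 lower and 1 higher when adjusted over the list alone. The camera adjusted p was 6.04e-07, and 0.0208 with an estimated correlation. Cd4 kept its call in 4 of the 10 fits without 1 library, those without wild-type 1 or 4 or labelled knockout 1 or 3 (edgeR adjusted p up to 0.0913 in the others). Of 10 markers of Kupffer cells, the macrophages of the liver, 5 were lower and 2 higher (6 and 2 when adjusted over the list alone). Cd5l, Timd4 (-2.05, edgeR adjusted p = 0.000120), Folr2, Clec4f (-1.07, 0.00930) and Vsig4 were lower, and the langerin gene Cd207 (12.8 ± 3.64 against 0.613 ± 0.188 CPM, 4.38, SE 0.25, 1.00e-06) and C6 were higher. C6 is also counted above among the male-biased genes, and Cd5l among the LXR targets. Camera gave an adjusted p of 0.000134 for the Kupffer cell list, and 0.192 with an estimated correlation. The Vsig4 call held in 3 of the 10 fits without 1 library, those without wild-type 1 or 3 or labelled knockout 5 (edgeR adjusted p up to 0.109 in the others). General macrophage markers were lower for 2 of 14, Mpeg1 and Adgre1 (6 when adjusted over the list alone, camera adjusted p = 0.000123, and 0.341 with an estimated correlation). The Adgre1 call was lost in 3 of 22 alternatives (edgeR adjusted p up to 0.0670).

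The acute phase genes Saa1, Saa2, Saa3 and Lcn2 were raised in the livers of labelled knockout mice 4 and 5 and not in the other 3. Serum amyloid gene Saa1 stood at 7910.0 and 14757 CPM in these 2 livers and at 45.3, 90.7 and 111 CPM in labelled knockout 1, 2 and 3, against 52.6 to 109 CPM in wild type. Saa2, Saa3 and Lcn2 were also highest in these 2 livers, and Saa3 stood at 2848.5 CPM in liver 5 against 318.8 in liver 4, so the group means of these 4 genes describe 1 or 2 libraries rather than the group. Of this list, 6 of 16 were higher and 1 lower (7 and 1 when adjusted over the list alone, camera adjusted p = 0.0329, and 0.555 with an estimated correlation). The lower gene, Cxcl10, stood at 2.64 ± 0.468 against 4.99 ± 0.805 CPM without overlap (-0.92, edgeR adjusted p = 0.00915), a call that was lost with all 20 libraries in 1 fit (0.110). The calls of Saa1, Saa2, Saa3 and Lcn2 were also lost without any 1 wild-type library (edgeR adjusted p up to 0.0982), and that of the list without wild-type 3, 4, 5 or 6 (camera adjusted p between 0.0510 and 0.0967), without labelled knockout 4 (0.169) or without labelled knockout 5 (0.249). Without both libraries Saa1 differed by 0.14 and Saa2 by -1.14, and neither was called (edgeR adjusted p = 0.863 and 0.109); the camera call then pointed towards lower (adjusted p = 0.0201). Over all genes, 636 were called in liver without these libraries, of which 473 were among the 893.

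**Figure D3:**
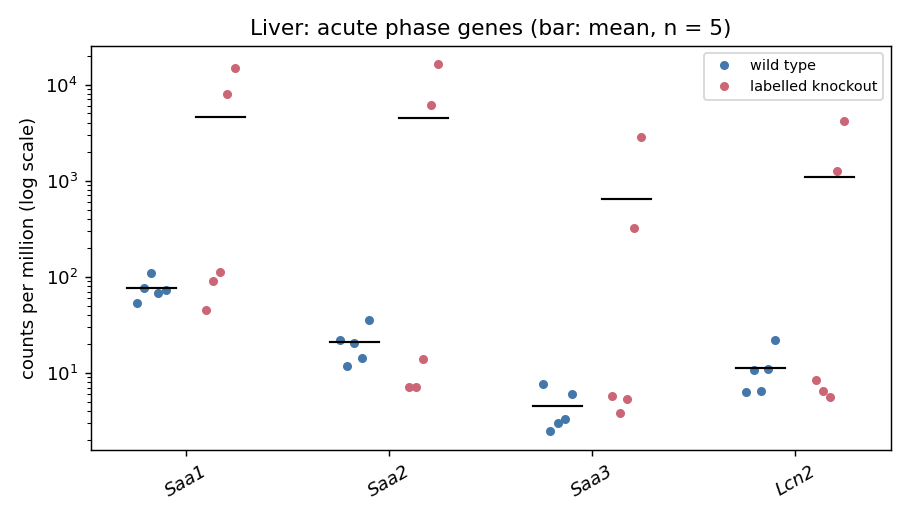
Liver CPM on a log axis for the acute phase genes Saa1, Saa2, Saa3 and Lcn2, with 1 point per library and bars for the mean (n = 5). Labelled knockout livers 4 and 5 lie far above the other 3, which lie near the wild-type livers.

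Camera called 4 further lists in liver, none of them with an estimated correlation. Endoplasmic reticulum stress genes were higher for 5 of 13 (7 higher and 1 lower when adjusted over the list alone), led by the asparagine synthetase Asns (2.34, SE 0.28, edgeR adjusted p = 0.000446), with a camera adjusted p of 0.000255, and 0.135 with an estimated correlation. Matrix genes were lower for 6 of 14 (7 when adjusted over the list alone), with Col1a1 at -1.74 (edgeR adjusted p = 0.00203), a camera adjusted p of 2.58e-06, and 0.199 with an estimated correlation. Proliferation genes were lower for 4 of 12 (7 when adjusted over the list alone), with Rrm2 at -1.49 (0.00529), a camera adjusted p of 7.02e-06, and 0.258 with an estimated correlation. Endothelial markers had a median of -0.30 with 1 of 10 called, Cdh5 (2 lower when adjusted over the list alone, camera adjusted p = 0.0193, and 0.542 with an estimated correlation). That camera call was lost without wild-type 5 (adjusted p = 0.0926), labelled knockout 1 (0.0635) or labelled knockout 4 (0.106), without labelled knockout livers 4 and 5 together (0.255) and by fry (0.152), and the Cdh5 call in 6 of the 10 fits without 1 library, namely wild-type 4, 5 or 6 or labelled knockout 1, 4 or 5 (edgeR adjusted p up to 0.0941). Camera called 15 of 29 tested lists in liver, 4 towards higher and 11 towards lower, of which 6 held with an estimated correlation. The number of called genes was 575 without wild-type library 6, and between 612 and 913 without any other single library.

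**Figure D4:**
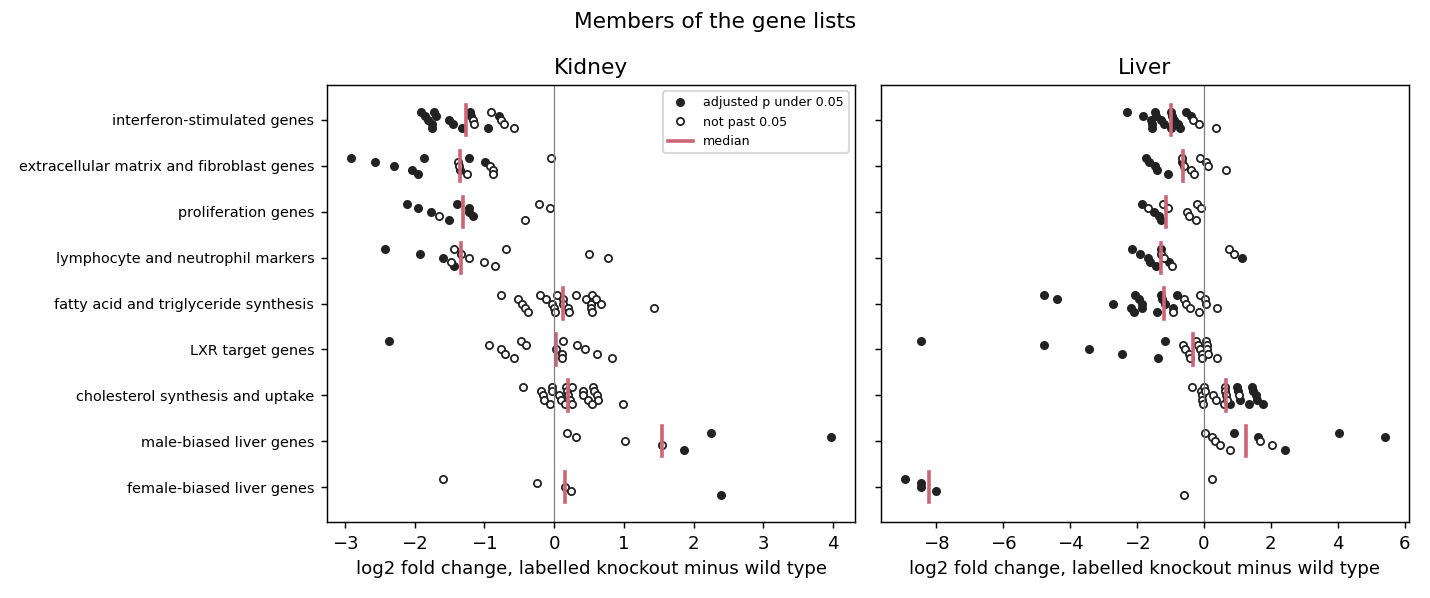
Log2 fold changes of the members of 9 gene lists in kidney (left) and liver (right), with filled points for genes called at an adjusted p under 0.05, open points for the rest and a bar at the median of each list. Interferon-stimulated genes lie below 0 in both tissues except 1 gene in liver, and genes of fatty acid synthesis lie mostly below 0 in liver alone, where the difference between tissues was tested by the interaction.

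The difference between the tissues was tested as the genotype effect in kidney minus that in liver, in 1 fit of all 20 libraries. Of 17606 genes, 265 differed, 165 with a more positive effect in kidney and 100 with a more negative one. Genes called lower in labelled knockout liver led the positive side: Cyp2a4 (11.37, SE 0.77, edgeR adjusted p = 1.34e-08), Cyp2b10 (10.57, SE 1.24, 3.55e-05), Cyp2b9 (9.51, SE 1.23, 0.000103) and Hao2 (7.82, SE 1.08, 0.000233). Cyp2b10, from the drug metabolism list, had a liver log2 fold change of -4.95, so the liver fall alone does not give its difference between tissues. Cyp2a4 was called in opposite directions, higher in labelled knockout kidney and lower in labelled knockout liver. On the negative side stood Moxd1, Obp2a (-10.49, SE 1.98, 0.00900), Ccr3 (-6.50, SE 1.59, 0.0473), Dct (-6.26, SE 0.91, 0.000413) and Irx1 (-6.04, SE 0.85, 0.000307), all higher in labelled knockout liver. Moxd1 was called (edgeR adjusted p = 0.00337), but its fitted value has no meaning with 0 wild-type counts in liver. Of 24 genes of fatty acid and triglyceride synthesis, 12 had a more positive effect in kidney (17 when adjusted over the list alone), including Scd1 (4.04, SE 0.64, 0.00105) and Acaca (2.02, 1.89e-05), with a camera adjusted p of 1.71e-25, and 0.00145 with an estimated correlation. Of 20 LXR target genes, 4 had a more positive effect in kidney and 1 a more negative one (7 and 1 when adjusted over the list alone, camera adjusted p = 0.000697, and 0.0701 with an estimated correlation). Of 7 female-biased genes, 4 had a more positive effect in kidney (5 when adjusted over the list alone, camera adjusted p = 3.40e-19, and 0.000345 with an estimated correlation). Male-biased genes had a median of -1.37, while camera pointed towards more positive without calling the list (adjusted p = 0.923). For interferon-stimulated genes no member differed between the tissues by edgeR (3 more negative in kidney when adjusted over the list alone), and the camera adjusted p was 0.0406, and 0.631 with an estimated correlation. This fit does not use the pairing of kidney and liver by mouse, which was taken from equal genotype and title number. With the mouse as a replicate block, 181 genes were called, 114 more positive and 67 more negative in kidney. Of these, 158 were among the 265. Among the named genes, that block ended the calls of Ccr3 (edgeR adjusted p = 0.172) and Ddb2 (0.0676). The count was 148 and 137 without wild-type mouse 4 and 5, and 171, 171, 138 and 151 without labelled knockout mouse 1, 3, 4 and 5; the Ccr3 call held only without wild-type mouse 5 or 6, that of Obp2a was lost without wild-type mouse 5 (edgeR adjusted p = 0.122), and that of Ddb2 without wild-type mouse 5 or labelled knockout mouse 1, 2, 4 or 5 (up to 0.0707).

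Across the 13912 genes tested in both tissues, the fold changes had a Pearson r of 0.22 and a Spearman rho of 0.19, where genes are not independent replicates. Genes called lower in both numbered 95, those called higher in both numbered 7, and 4 genes were called in opposite directions. Both tissues were taken to come from the same mice, so no overlap by chance is given. Those with the smallest p in both tissues were Acp2, Cyp2a4, Irf7, Ddb2, Usp18, Ms4a4b, Slfn9, Col1a1, Nr1h3 and Ifi213. Ms4a4b, a lymphocyte membrane gene, fell by 2.49 in kidney and 1.87 in liver (edgeR adjusted p = 0.00273 and 0.000714), Slfn9 by 2.16 and 1.51 (0.00250 and 0.00148), and Ifi213 by 2.33 and 1.95 (0.0109 and 0.000551). In kidney, Usp18 stood at -1.45 (0.0237), a call that was lost without wild-type 5 or labelled knockout 1 or 4 (edgeR adjusted p up to 0.0797).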

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

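Tests of sex genes, of the 2 wild-type kidneys that stand apart, of tubule share, of flanking DNA and of Acp2 reads, and the splits counted list by list, were chosen only after the results were seen; the others were not. The fetal and juvenile list was added after the genotype results were seen, though before its own values in liver were.

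Of 250 groups of 5 values, 26 held a library far from the other 4. The rule flags about 1 in 20 groups where values are normally distributed and groups independent. That was not shown for these values, and the same libraries recur, so the number does not show an excess. Labelled knockout liver 4 had the highest total, 35376342 counts. Wild-type kidney 3 had a median Spearman rho of 0.882 to the other kidneys, and stood apart in Oas2 (30.8 CPM), Ddb2 (15.9 CPM) and Usp18 (7.85 CPM). Wild-type kidney 5 stood apart in Prlr (70.8 CPM) and Chrdl1 (0.212 CPM), labelled knockout kidney 4 in Col19a1 (3.28 CPM) and labelled knockout kidney 2 in Mki67 (9.77 CPM). Wild-type liver 5 was high in the female-biased genes Cyp2a4 (696 CPM) and Cyp2b9 (153 CPM), and in Slc22a26 (68.3 CPM), Slc22a27 (21.3 CPM) and Sdf2l1 (47.1 CPM). Wild-type liver 4 was high in Obp2a (0.141 CPM), Mup17 (258 CPM) and Angptl4 (109.5 CPM). Labelled knockout liver 5 was high in Cyp21a1 (5.67 CPM), Cd207 (19.2 CPM), Saa3 (2848.5 CPM) and Creld2 (125 CPM), labelled knockout liver 3 in Cyp4a14 (13.4 CPM), Col1a2 (22.6 CPM) and Col3a1 (56.3 CPM), and labelled knockout livers 4 and 2 in Mup19 (342 CPM) and Acot3 (0.545 CPM).

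Of 101 named genes, 27 differed between tissues by the interaction test of edgeR, given here as the log2 effect in kidney minus that in liver. Lipid genes with positive values were Scd1 (4.04), Cd36 (3.36), Me1 (2.62), Pltp (2.51), Elovl5 (2.08), Acaca (2.02) and Rnf145 (2.02). Genes of the female-biased list were Cyp2a4 (11.37), Cyp2b9 (9.51) and Hao2 (7.82). Cyp2b10 (10.57), Slc22a26 (7.70), Kcna2 (6.84) and Slc22a27 (4.66), which are not in that list, had positive values as well. Cyp4a12a (3.51), Azgp1 (3.04), Chrdl1 (3.01) and Apoh (2.81) were positive too. Negative values were those of Moxd1 (-14.87, fitted against 0 counts), Obp2a (-10.49), Ccr3 (-6.50, a call lost in 8 of 10 fits without 1 mouse), Dct (-6.26), Irx1 (-6.04), Cd207 (-5.37), Cd4 (-2.55), Cyp7b1 (-2.48) and Ddb2 (-1.17, lost in 5 of 10).

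Other splits of the 10 mice into 5 and 5 were fitted, 100 of 126 with the real one included. Chance is argued against for the number of called genes, where only the real split gave such counts, 1 of 100 each. The counts were 373 in kidney against at most 1 and 893 in liver against at most 2. For the difference between tissues the count was 265 against at most 1. With 100 splits drawn, no smaller share was possible. Every other split mixed the genotypes, which adds any difference between them to the spread within groups. The margin is therefore partly built in. Chance is left open for the correlation across tissues (0.22 against up to 0.359, 24 of 100 splits as large). The same holds for the number of called lists (17 in kidney against up to 20, 11 of 100, and 15 in liver against up to 17, 7 of 100). Counted list by list, the interferon, matrix, male-biased, proximal tubule and transporter lists in kidney and the interferon, LXR, fatty acid synthesis, male-biased and female-biased lists in liver had a test as small in the real split alone (1 of 100 splits each), whereas others were matched more often. In liver these were acute phase (46 of 100), endothelial (43), proliferation (19), macrophage (18), cholesterol synthesis (12), matrix (11) and fatty acid oxidation (9), and Kupffer cell, endoplasmic reticulum stress (3 each) and lymphocyte lists (2). In kidney they were immediate early genes (85), fatty acid oxidation (45), fatty acid synthesis (35), cholesterol synthesis (27), drug metabolism (26), macrophage (21), endoplasmic reticulum stress (18), endothelial (8), glomerular (5), lymphocyte (3), proliferation and bile acid lists (2 each). Some lists share members, among them the male-biased, proximal tubule and transporter lists, so their counts are not independent.

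Some sex-biased genes differed by genotype among mice labelled male, with 4 of 6 female-biased genes lower and 5 of 12 male-biased genes higher in labelled knockout liver. Females among the mice are argued against by Xist, at most 0.342 CPM in any library, with Ddx3y at least 20.3 CPM. A single mouse as the source is argued against too, since the female-biased list was called by camera without any 1 liver library (highest adjusted p = 9.31e-11). Fetal and juvenile genes had a median of -0.53 in liver, with 3 of 9 lower and none higher (camera p = 0.000929, and 0.0323 with an estimated correlation), but of -0.21 in kidney, with 1 of 11 lower and 1 higher (camera p = 0.171). In liver 9 of 17 listed genes were tested, of which 8 were negative. Afp (-0.14), Gpc3 (-0.08) and Peg3 (0.11) were among those not called. Meg3 and Rian, imprinted genes outside this list, were higher in labelled knockout liver. The liver median goes with wild-type mice that were younger or less mature, but it rests on few genes and does not show this. In kidney camera also pointed towards lower, with 7 of 11 genes negative, but its p was not under 0.05. The kidney value therefore neither adds to this reading nor argues against it. With no ages in the labels both age and genotype stay open.

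In labelled knockout kidney 14 of 20 interferon, 9 of 16 matrix and 8 of 12 proliferation genes were lower, though camera called none of these lists with an estimated correlation (adjusted p from 0.0699 to 0.120). The 2 wild-type libraries that stand apart do not carry this, since without both the median of the interferon list was -1.33. A lower share of proximal tubule in wild-type kidney would raise markers of all other cell types alike. Distal tubule and collecting duct markers had a median of -0.12 over 27 genes, and endothelial and glomerular markers -0.80 over 19 (permutation p = 4e-05). The permutation shuffled genes, which are not independent within the same kidneys, so its p does not measure the spread between mice. It therefore does not decide on the proximal tubule share. That share, a change in particular cell types, genotype and age stay open, and no test here separates them.

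Nr1h3, Acp2 and Ddb2 were higher together in the labelled knockout. A fixed share of Acp2 reads counted for Ddb2 cannot raise Ddb2 over Acp2, and is argued against in liver, where Ddb2 over Acp2 was 0.205 ± 0.0243 against 0.110 ± 0.0285 in wild type (n = 5, exact permutation p = 0.00794). In kidney it stays open, at 0.214 ± 0.0239 against 0.274 ± 0.0948 (n = 5, exact permutation p = 0.111). Flanking DNA of another strain cannot be told apart from an effect of the allele itself, because the calls near Nr1h3 were too few to decide (Fisher's exact p = 0.137 in kidney). Those calls also include Acp2 and Ddb2 themselves. Which part of Nr1h3 was removed is not in the labels, so a transcript that stays or is read through from the altered allele remains open and untested.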

How the results depend on the processing

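Fits without wild-type kidneys 1 and 3, without labelled knockout livers 4 and 5 and without mitochondrial genes were chosen after the results were seen; the other alternatives were not. Nr1h3 in kidney, KO against WT, stayed called and higher under every alternative, at 1.19 to 1.35, and Nr1h3 in liver at 0.67 to 0.84. The genes changed in kidney, KO against WT, 373, came to 1151 by DESeq2, 2151 by voom with quality weights, 948 with all 20 libraries in 1 fit, 237 on log2 FPKM, 902 with the replicate block and 590 without wild-type kidneys 1 and 3, and ranged from 99 to 921 without 1 library. The genes changed in liver, KO against WT, 893, came to 1408 by DESeq2 and 307 with the replicate block, and ranged from 575 to 913 without 1 library. The genes whose genotype effect differs between kidney and liver, 265, came to 611 by DESeq2, 681 by voom and 176 without TMM. They came to 181 with the mouse as a replicate block, and ranged from 137 to 337 without 1 mouse. With an estimated correlation, 0 of 17 called lists held in kidney and 6 of 15 in liver. For all these counts the cause was not tested. Equal-numbered libraries of different genotype had residual correlations of 0.0586 to 0.164 in kidney (mean 0.103, against -0.0214 over 16 unequal pairs) and -0.0419 to 0.0493 in liver (mean -0.0114 against 0.00302), and 1 of 4 labelled knockout kidneys and 0 of 4 livers correlated best with its own number. With that block, calls lost among genes named in the text were those of Cd4, Cd3g, Gzma and Nkg7 in kidney and, with adjusted p, Srebf1 in liver (0.139), Sqle in liver (0.0587), Slc10a1 in liver (0.0697), Abcb4 in liver (0.148), Adgre1 in liver (0.0670), Cxcl10 in liver (0.0586), Cdh5 in liver (0.106), Vsig4 in liver (0.0588), Cd4 in liver (0.201), Igf2bp3 in liver (0.0917), Plagl1 in liver (0.128) and the 4 acute phase genes. Other calls lost, with adjusted p, were Cdh5 in kidney (0.0582), Slc22a6 in kidney (0.0961), Cd4 in liver (0.0504) and Ccr3 between tissues (0.0599) without TMM, and Slc22a6 in kidney (0.0597), Abcb4 in liver (0.0568) and Ccr3 between tissues (0.0586) with no filter. With all 20 libraries in 1 fit they were Abcb4 in liver (0.190), Angptl4 in liver (0.0847), Adgre1 in liver (0.0612), Cxcl10 in liver (0.110) and Vsig4 in liver (0.0614), and with RLE size factors Abcb4 in liver (0.0551). On log2 FPKM they were Gzma in kidney (0.0857), Cdh5 in kidney (0.0513), Lcn2 in liver (0.424) and Igf2bp3 in liver (0.0515), and by voom Mup8 in liver (0.0672), Saa1 in liver (0.584), Saa2 in liver (0.898), Saa3 in liver (0.523) and Lcn2 in liver (0.751). Without wild-type kidneys 1 and 3, Cdh5 in kidney (0.0557) was lost, and without labelled knockout livers 4 and 5, Mup17 in liver (0.0646), Srebf1 in liver (0.0728), Sqle in liver (0.0541), Abcb4 in liver (0.152), Adgre1 in liver (0.0538), Cdh5 in liver (0.122), Cd4 in liver (0.0886) and Plagl1 in liver (0.108). By fry, lists lost were fatty acid synthesis (0.278), cholesterol synthesis (0.167), fatty acid oxidation (0.340), drug metabolism (0.204), immediate early genes (0.278) and endoplasmic reticulum stress (0.0959) in kidney, and acute phase (0.396) and endothelial markers (0.152) in liver. Reversed signs were those of Nr1h2 in kidney (-0.013 with the replicate block, -0.0298 without wild-type 6, -0.0046 without labelled knockout 3; -0.0298 to 0.26 without 1 library), Nr1h2 in liver (0.0065 without wild-type 1; -0.13 to 0.0065) and Cyp7a1 in liver (-0.36 with the replicate block, -0.093 without wild-type 1, -0.38 without labelled knockout 2; -0.38 to 0.26), none of them called. Without labelled knockout livers 4 and 5, Saa2 in liver (-1.14), Lcn2 in liver (-0.72) and the list inflammation and acute phase in liver (adjusted p = 0.0201, towards lower) reversed, since the rise lay in those libraries. Depth limits genes with under 10 counts in a group, such as Hao2, Kcna2, Obp2a and Cyp21a1, whose fold changes are uncertain.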

Other observations

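The windows, their tests and the genes named in these 2 paragraphs were chosen after the results were seen, whereas the fetal and juvenile list was added after the genotype results but before its own values in liver were seen. Genes called in liver were clustered along the chromosomes. Of 534 windows of 5 Mb, the one on chromosome 4 from 60000001 to 65000000 held 21 called genes of 52 tested, all higher in labelled knockout liver (Fisher's exact p after BH = 3.27e-10). They are members of the Mup family of urinary proteins, pseudogenes among them, with Orm2 and Gm13773. The window on chromosome 19 from 30000001 to 35000000 held 10 called of 27, all lower (0.000527), among them the interferon-stimulated genes Ifit1, Ifit2 and Ifit3 and the lipase genes Lipa and Lipo3. The window on chromosome 1 from 170000001 to 175000000 held 15 called of 77, of which 14 were lower (0.00829), including Ifi204 (-1.23), Ifi209 (-1.48) and Ifi213 (-1.95) of the interferon-inducible p200 family. Members of the Mup, Ifit and p200 families resemble each other, so reads can be assigned to the wrong member, and neighbours are not independent.

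Some imprinted and fetal genes also differed. Meg3, a maternally expressed long RNA, stood at 48.6 ± 37.5 CPM in labelled knockout liver against 1.21 ± 0.340 in wild type (n = 5, log2 fold change 5.31, edgeR adjusted p = 0.000151), and Rian of the same imprinted cluster rose by 5.23 (edgeR adjusted p = 0.000383). In kidney, Meg3 differed by -0.62 and was not called (edgeR adjusted p = 0.521). H19 (-4.52, edgeR adjusted p = 0.00516), Igf2bp3 (-2.29) and Plagl1 (-1.06), genes of fetal liver that fall after birth, were lower in labelled knockout liver. They were 3 of 9 tested fetal and juvenile genes, and Mest, Cdkn1c, Grb10, Peg3 (0.11), Afp (-0.14) and Gpc3 were not called in liver (edgeR adjusted p from 0.0702 to 0.959). In kidney, 1 of 11 was lower and 1 higher: Plagl1 was lower (-1.22) and Igf2bp1 higher (1.55). The Plagl1 call was lost without wild-type 6 or labelled knockout 4 in liver (edgeR adjusted p up to 0.0618) and without wild-type 5 or labelled knockout 1, 3, 4 or 5 in kidney (up to 0.0831).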
